A study of Mus musculus with 15 samples.

How the data were processed

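RNA of isolated left-ventricular cardiomyocytes was measured on Affymetrix Mouse Gene 1.0 ST arrays. The cells had been freed by perfusion of the heart with collagenase and brought back to calcium in steps, and the labels state that the suspension could hold some inflammatory and endothelial cells. Only the proton arrays were part of this series; the design text also names iron ions, for which no samples were present. The deposited table holds log2 signals for 34760 probe sets and 15 arrays, from 0.123 to 12.9. The authors' notes name MAS5, with no version, and do not describe background correction or normalization; the 95th percentiles of the arrays lay between 9.11 and 9.16, so a scaling between arrays had been made. The values were used as they were. No count of depth exists for arrays.

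Probe sets were joined to genes by the annotation of the array: 21640 carried 1 symbol, 1321 carried several and 11799 had no entry. Of the single-symbol probe sets, 21553 matched the RefSeq gene table of GRCm38.p6, which gave the positions. For each gene, the probe set with the highest mean was used among those with 1 symbol (954 genes had several), and genes were kept when that mean was above the median of all probe sets, 5.00, which left 12102 genes.

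Samples were grouped by treatment and by the day in their titles, and the 3 sham samples (2 of day 1, 1 of day 3) were pooled as the control of every day, since days 5, 12 and 26 have no sham of their own. Proton day 5 replicates 1 and 2 had a Spearman correlation of 0.989, against at most 0.978 for any other pair, and were averaged as 1 sample. The plan had named all 15 arrays as separate samples; this departure was made after the values were seen, and the 15-array result stands among the alternatives. The replicate numbers did not pair the samples: of 26 pairs of the same number in different groups, correlations of residuals had a median of -0.083 and 9 were above 0.1.

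Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on 14 samples in 6 groups, with 8 residual degrees of freedom and 12.1 in the moderated test. Contrasts were each proton day minus sham, the mean of days 12 and 26 minus the mean of days 1 and 3 (late minus early), and F-tests for any proton day against sham and for any difference among the 5 proton days. p-values were adjusted by Benjamini-Hochberg over all genes tested, at 0.05. Fold changes carry the standard error of the fit, and group values carry the SD.

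The comparisons, the tests, 39 gene lists and the rule for named genes were fixed before the data were examined. The lists cover radiation and stress responses (p53 targets, DNA double-strand break repair, cell cycle, oxidative stress defence, unfolded protein response, heat shock, apoptosis, immediate early genes, autophagy), inflammation and matrix, cardiac structure, calcium and ion channels, metabolism, ribosome, clock and glucocorticoid genes, and markers of 10 other cell types and of atrial and conduction cells. The rule named, for each contrast, up to 8 passing genes in each direction whose samples did not overlap the control, the 5 genes with the smallest p where fewer than 5 passed, up to 4 members of each list past the threshold or else up to 2 with the largest change, the 10 smallest p of each F-test, and 17 fixed genes. Names outside it are said to have been chosen after the values were seen. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 39 lists. Genes of a list were also adjusted over the list alone.

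List means per sample (deviations from each gene's mean) were compared by exact permutation over all 364 splits into 11 and 3 samples, or all 126 splits into 4 and 5 samples, 2-sided, in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. A score of non-cardiomyocyte cells was the mean of the endothelial, fibroblast and macrophage lists. The procedure was tested on simulated data: of genes with an inserted log2 difference of 1, 81.4% were recovered at the group sizes of day 5, 85.5% at those of day 3 and 87.3% at those of day 26, and of those with 0.5, 38.8%, 44.4% and 34.4%. Genes without an inserted difference gave 8, 11 and 7 false calls at these sizes. The simulated genes varied independently, unlike the real ones, and many were changed at once, which eases the adjusted threshold. These rates may thus overstate the recovery in the real data. Camera's lists were tested on 100 simulated data sets that kept the residual covariance of the samples and held no group difference.

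Alternatives were quantile normalization, equal array medians, no filter or a stricter filter at the 75th percentile, all probe sets, the mean of a gene's probe sets, no variance trend, a robust variance, array weights, a test without shared spread, a fit of only the groups compared, sham of day 1 only, time-matched sham, a replicate block (without the sham day 3 sample) and leaving out each array in turn. All 15 arrays as separate samples and the non-cardiomyocyte score as a covariate were added after the data had been seen. The 2 planned pseudocounts were not run, since the values were already logarithms. No sample was tested for lying far from the others, since groups held 2 or 3 samples.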

Results

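Gene expression was measured with 15 microarrays in cardiomyocytes isolated from the left ventricle of adult male C57Bl/6NT mice, a common inbred laboratory strain. The mice had received 90 cGy of 1 GeV protons to the whole body or a sham treatment. By the sample titles, 2 arrays came from day 1 after protons, 3 from day 3, 3 from day 5, 2 from day 12 and 2 from day 26. Sham cells gave 2 arrays at day 1 and 1 array at day 3. The design text of the series names days 1, 3, 7, 14 and 28 instead, and the days of the titles are used here. Each array gave a log2 signal for 34760 probe sets, with array medians from 4.90 to 5.16, and the number of arrays limits the precision of every value below. Proton day 5 replicates 1 and 2 were nearly the same array by value: the SD of their log2 differences was 0.0768, against 0.222 to 0.527 for every other pair of the 105 pairs. They were averaged, which left 14 samples. The labels do not say whether the arrays of a group came from different mice, so every p-value measures only the spread between these samples.

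The first comparisons ask how cardiomyocytes differed from the pooled 3 sham samples at each day after protons. Of 12102 genes tested with limma, few passed an adjusted p of 0.05 on any day. The count was 0 at day 1, 1 at day 3, 6 at day 5, 0 at day 12 and 5 at day 26. It depended on the settings: with the marker score of other cells as a covariate it was 3, 107, 17, 1 and 126 at these days, with array weights 1, 4, 47, 0 and 309, and with all 15 arrays as separate samples 0, 5, 32, 2 and 54. The clearest single genes were Pde7a, a phosphodiesterase that breaks down cAMP, the small nuclear RNAs Scarna13 and Rnu12, and Sdf2l1, a chaperone cofactor of the endoplasmic reticulum. Gene lists fixed beforehand were tested with camera; in 100 simulated data sets with the correlation of these samples and no group difference, camera with its preset correlation called a median of 12.5 to 14.5 of the 39 lists, so its calls are given below with the p that an estimated correlation leaves. Leaving out 1 array moved the medians of 78 of the 98 called lists by over 1.5 times or past 0. In a test for a difference from sham on any of the 5 days, Pde7a (adjusted p = 0.0117), Scarna13 (adjusted p = 0.0418) and Rnu12 (adjusted p = 0.0418) passed. The next in rank did not pass: Sdf2l1, Lcn2, Ctnnal1, Rnf144b and Car14 shared an adjusted p of 0.108, Snora16a had 0.119 and Ehd4 had 0.142. At an unadjusted p under 0.05 this test counted 1154 genes, where 605 would be expected by chance, and the test without shared spread passed 1 gene. The count of 3 became 0 without proton day 1 replicate 1, proton day 3 replicate 1, either proton day 26 replicate or sham day 1 replicate 1. It was 1 without proton day 1 replicate 2, proton day 3 replicate 2 or proton day 5 replicate 3, 5 without proton day 3 replicate 3 or proton day 12 replicate 1, 6 without proton day 12 replicate 2, and 8 without sham day 3 replicate 1.

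**Figure D1:**
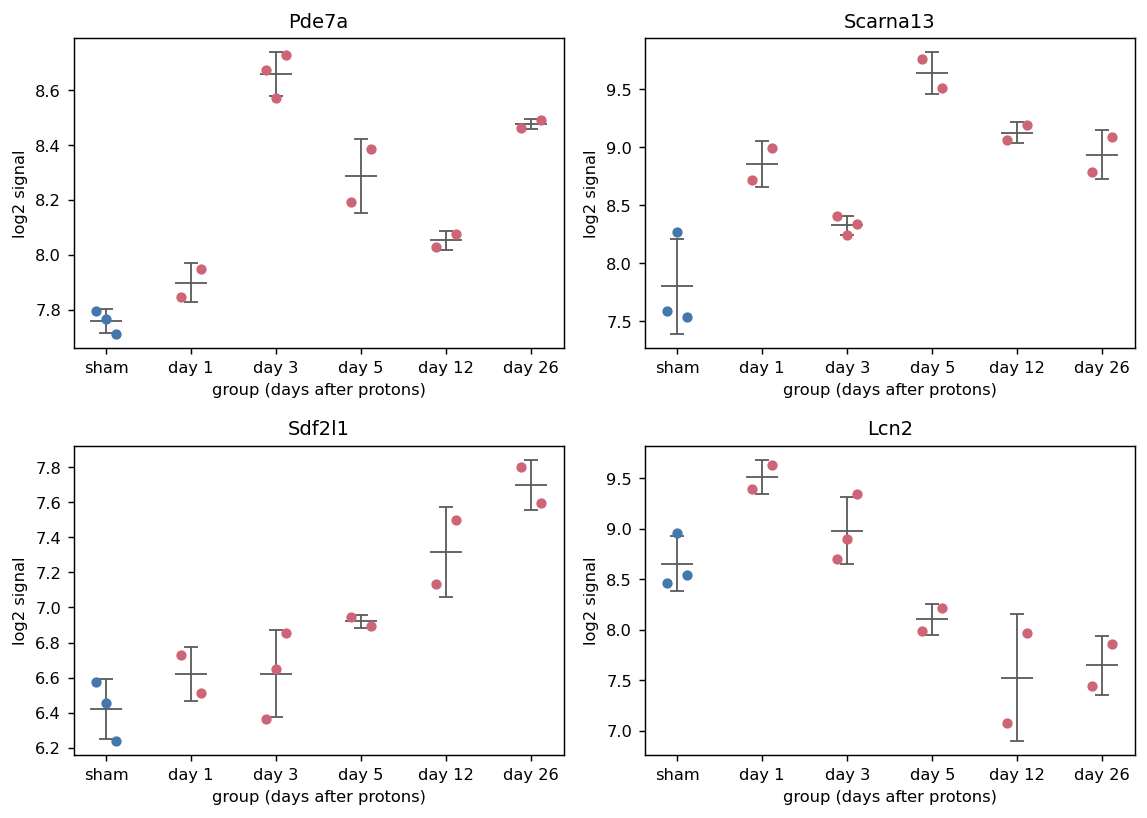
Log2 signal of Pde7a, Scarna13, Sdf2l1 and Lcn2 (y axes) in sham samples and at each day after protons (x axes). Points are samples, long bars are group means and short bars are 1 SD; Pde7a had a mean of 8.66 at day 3 and 7.76 in sham, and Lcn2 had a mean of 7.59 over the 4 late samples and 9.19 over the 5 early samples.

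At day 1 no gene passed, and the 5 smallest p-values belonged to 3 small RNAs and 2 protein-coding genes. Rnu12, the U12 RNA of the minor spliceosome, was at 7.64 ± 0.14 (SD, n = 2) against 6.29 ± 0.28 in sham (SD, n = 3), a log2 difference of 1.35 ± 0.19 (SE; limma adjusted p = 0.172). Scarna13, a small RNA of Cajal bodies, had a difference of 1.06 ± 0.19, and the H/ACA box RNA Snora16a had 0.99 ± 0.19. The zinc transporter Slc30a5 had 0.62 ± 0.11 and Pkdrej had 0.64 ± 0.12, and these 4 genes shared an adjusted p of 0.474. Limma passed 0 genes, with 666 at an unadjusted p under 0.05 where 605 would be expected by chance, and the test without shared spread also passed 0. The count was 1 without proton day 3 replicate 3 or without sham day 1 replicate 2.

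Markers of blood and other heart cells had higher values at day 1. Macrophage and monocyte markers had a median log2 difference of 0.66, with 22 of 23 measured genes above sham, among them Itgam (1.60 ± 0.57) and Cd14 (1.23 ± 0.45). The list was called higher by camera (adjusted p = 3.68e-07), and the call was lost (adjusted p = 0.647 with an estimated correlation). Neutrophil markers, of which 6 of 15 were measured, had a median of 0.80. Ltf, the neutrophil granule protein lactoferrin, was at 3.10 ± 0.94 and Retnlg at 1.91 ± 1.04. In sham Ltf was at 4.45, below the signal filter, so higher values in proton samples brought it past the filter. Ltf and Csf3r passed when adjusted over the list alone and none passed over all genes. Erythroid and platelet markers had a median of 0.91 (Alas2 1.55 ± 0.87, Bpgm 1.40 ± 0.58), mesothelial and epicardial markers 0.76 (Muc16 1.22 ± 0.74, Upk1b 0.96 ± 0.68), fibroblast markers 0.43 (Mmp2 0.84 ± 0.35, Lum 0.83 ± 0.36), lymphocyte markers 0.36 (Jchain 1.29 ± 0.75, Cd8b1 0.95 ± 0.55) and endothelial markers 0.28 (Vwf 1.35 ± 0.41, Mmrn2 0.76 ± 0.39). Camera called these 6 lists higher as well, each lost (lowest adjusted p = 0.647 with an estimated correlation). Proton day 1 replicate 2 stood above replicate 1 in macrophage (list means 0.75 and 0.16), neutrophil (1.62 and 0.31) and erythroid (1.57 and 0.65) markers. Without it the medians were 0.40 for macrophage, 0.27 for fibroblast and 0.47 for mesothelial markers, and 0.11 for neutrophil, 0.36 for erythroid and 0.125 for endothelial markers, which camera then did not call. Without replicate 1 the lymphocyte median was 0.09 and not called.

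Inflammatory and matrix lists moved at day 1 together with those markers. Camera called higher the lists of complement and antigen presentation (median 0.52, with C1s1 0.87 ± 0.67, Cfb 0.73 ± 0.51), STAT3 and acute phase genes (0.36, with Hp 1.57 ± 0.65, Saa3 1.50 ± 0.50), NF-kB cytokines and adhesion molecules (0.33, with Ccl7 1.08 ± 0.45, Vcam1 0.92 ± 0.55) and immediate early genes (0.31, with Egr2 0.63 ± 0.42, Nr4a2 0.47 ± 0.29). It also called higher TGF-beta signalling (0.26, with Thbs1 1.58 ± 0.67, Fn1 1.45 ± 0.59), extracellular matrix (0.28, with Fbln1 0.60 ± 0.38), the unfolded protein response (0.16, or 0.03 with the marker score of other cells as a covariate, with Edem1 0.50 ± 0.32) and p53 targets (0.08, with Trp53inp1 0.77 ± 0.26, Eda2r 0.59 ± 0.23). All 8 calls were lost (lowest adjusted p = 0.647 with an estimated correlation). The lists called lower had small medians: cytosolic heat shock proteins -0.12, oxidative phosphorylation complex I -0.09, complexes II to V -0.08 and cytosolic ribosomal proteins -0.09. These were lost too (lowest adjusted p = 0.647 with an estimated correlation). Without proton day 1 replicate 2 the medians were 0.20 for STAT3 and acute phase genes, 0.24 for complement, 0.10 for extracellular matrix and -0.04 for complex I, and camera did not call the last 3 or the NF-kB list. The p53 list was not called without replicate 1 or without replicate 2. Among p53 targets, Phlda3, a repressor of Akt signalling, was 0.51 ± 0.12 above sham and passed limma when adjusted over the list alone (limma adjusted p = 0.0235) but not over all genes (limma adjusted p = 0.754).

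At day 3, Pde7a rose. It lies on chromosome 3 from 19223108 to 19311322 (GRCm38.p6) and was at 8.66 ± 0.08 (SD, n = 3) against 7.76 ± 0.04 in sham (SD, n = 3), 1.87-fold higher (log2 0.90 ± 0.08 SE; limma adjusted p = 0.000965). All 3 day 3 samples lay above all 3 sham samples. The next 4 genes did not pass: the microRNA gene Mir504, inside Fgf13, at 0.78 ± 0.11 (adjusted p = 0.0503), Tmem88b at 1.02 ± 0.15 and the transcriptional regulator Ifrd1 at 0.55 ± 0.08 (both adjusted p = 0.0541), and Asb11 at 0.57 ± 0.10 (adjusted p = 0.11). Limma counted 1072 genes at an unadjusted p under 0.05. The count of 1 became 0 when only the sham and day 3 samples entered the fit (Pde7a adjusted p = 0.0688) or without shared spread (adjusted p = 0.394). It was 2 without proton day 5 replicate 2 or sham day 3 replicate 1, and 5 without proton day 12 replicate 1 or 2.

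Camera called 3 of the 39 lists at day 3, all higher and none of them a list of cell type markers. At least as many were called in 98 of the 100 simulated data sets without a group difference, so this number is no more than chance gives. The unfolded protein response, the set of genes that handles misfolded protein in the endoplasmic reticulum, had 25 of 26 measured genes above sham, with a median log2 difference of 0.24 (camera adjusted p = 3.01e-07; adjusted p = 0.978 with an estimated correlation). Herpud1, part of the degradation machinery of that compartment, was at 0.58 ± 0.12 and Chac1 at 0.53 ± 0.19. Herpud1 passed when adjusted over the list alone, and 0 of the 26 passed over all genes. Glucocorticoid-induced genes had a median of 0.24 (camera adjusted p = 0.0031; adjusted p = 0.978 with an estimated correlation). In that list, 5 genes passed when adjusted over the list alone and 0 over all genes: the metallothioneins Mt1 (0.37) and Mt2 (0.54), the transcription factors Zbtb16 (0.82) and Klf15 (0.47), and Glul (0.21). Autophagy and lysosome genes had a median of 0.10, with Fbxo32 at 0.42 ± 0.11 and Npc1 at 0.39 ± 0.13 (camera adjusted p = 0.0119; adjusted p = 0.978 with an estimated correlation). The endothelial (-0.11), macrophage (-0.18) and lymphocyte (-0.17) marker medians were below 0 at day 3, and the fibroblast median was 0.11. Proton day 3 replicate 3 stood apart from replicates 1 and 2 in the list means per sample: 0.49 against -0.89 and -0.72 for macrophage markers, 0.305 against -0.38 and -0.59 for endothelial markers, 0.16 against -0.14 and -0.06 for the unfolded protein response, and 0.52 against -0.14 and -0.04 for glucocorticoid-induced genes. Without it the unfolded protein response median was 0.155, while the glucocorticoid median was 0.002 and the autophagy median 0.07, neither called by camera.

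At day 5, small RNAs of the nucleus rose. Snora3 was 4.31-fold higher than in sham (log2 2.11 ± 0.29 SE), with a log2 difference of 1.37 in its second probe set, and the other H/ACA box RNAs Snora16a (1.44 ± 0.19) and Snora73b (1.40 ± 0.19) were 2.72-fold and 2.63-fold higher; such RNAs guide the conversion of uridine to pseudouridine or the processing of ribosomal RNA. Scarna13 was at 9.64 ± 0.18 (SD, n = 2) against 7.80 ± 0.41 (SD, n = 3), 3.58-fold higher (limma adjusted p = 0.00669). Rnu12 was 2.69-fold higher (log2 1.43 ± 0.19), and Tmem109, a channel protein of the endoplasmic reticulum membrane, was 1.56-fold higher (log2 0.65 ± 0.09). The other 5 genes shared an adjusted p of 0.0198, and every day 5 sample lay above every sham sample for all 6. The small RNA genes lie at chromosome 7, 109520132 to 109520251 (Snora3, within Rpl27a), chromosome 12, 105031075 to 105031349 (Scarna13, within Snhg10), chromosome 4, 132309465 to 132309600 (Snora16a, within Snhg12) and 132352322 to 132352526 (Snora73b, within Snhg3), and chromosome 15, 83149645 to 83149794 (Rnu12). Tmem109 lies on chromosome 19 from 10870657 to 10881743. These are the RefSeq positions of the genes. Which of the 2 Snora3 probe sets measures the site within Rpl27a was not checked. Rpl27a itself was at -0.23 ± 0.09, a gene looked at after the values were seen. Limma counted 1088 genes at an unadjusted p under 0.05, and 0 genes passed without shared spread. The count of 6 became 0 without proton day 5 replicate 3, 3 without either proton day 26 replicate or sham day 1 replicate 1, and 1 without a variance trend.

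Day 5 also had higher values for genes of the unfolded protein response. Of 26 measured genes, 25 were above sham with a median of 0.34, and 10 passed when adjusted over the list alone, among them the chaperone Hsp90b1 (0.61 ± 0.13), Chac1 (0.59 ± 0.21) and the transcription factor Xbp1 (0.41); 0 passed over all genes (camera adjusted p = 7.86e-12; adjusted p = 0.792 with an estimated correlation). Lymphocyte markers had a median of 0.27, with Cd8b1, a chain of the CD8 receptor of T cells, at 2.88 ± 0.55 (limma adjusted p = 0.174) and Jchain at 1.30 ± 0.75 (camera adjusted p = 0.000253; adjusted p = 0.538 with an estimated correlation). Camera also called higher the mesothelial (median 0.69, with Muc16 1.19 ± 0.74), fibroblast (0.38, with Thy1 0.96 ± 0.33), extracellular matrix (0.23, with Fmod 0.71 ± 0.46) and atrial (0.18, with Myl4 1.68 ± 0.79, Myl7 1.60 ± 0.63) lists. These 4 calls were lost (lowest adjusted p = 0.804 with an estimated correlation). The endothelial median was 0.06 and the macrophage median 0.26. Genes of muscle energy supply had small values below sham: the citric acid cycle had 18 of 21 genes below 0 (median -0.09, with Fh1 -0.32 ± 0.07, Suclg1 -0.31 ± 0.07). Camera called it lower (adjusted p = 2.22e-05; adjusted p = 0.804 with an estimated correlation), along with complex I (-0.11), complexes II to V (-0.08), sarcomere proteins (-0.10) and ribosomal proteins (-0.07). Those 4 calls were lost as well (lowest adjusted p = 0.804 with an estimated correlation). Without proton day 5 replicate 3 the lymphocyte median was 0.53, and the extracellular matrix (0.11), atrial (0.04) and ribosomal (-0.07) lists were not called.

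At day 12, no gene passed, and the smallest p-values belonged to a small RNA, a carbonic anhydrase, 2 clock genes and an endoplasmic reticulum gene. Scarna13 had a log2 difference of 1.33 ± 0.19 and Car14, a membrane carbonic anhydrase, of -0.50 ± 0.08, each with limma adjusted p = 0.136. The clock output gene Dbp was at 8.23 ± 0.11 (SD, n = 2) against 8.93 ± 0.07 in sham (SD, n = 3; log2 -0.70 ± 0.12), and the clock repressor Ciart was at -1.54 ± 0.28. Sdf2l1 was at 0.89 ± 0.16, and these 3 shared an adjusted p of 0.225 from limma. Limma passed 0 genes with 969 at an unadjusted p under 0.05, and the test without shared spread passed 0. The count was 1 without proton day 12 replicate 1 or without sham day 1 replicate 2.

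Of the unfolded protein response genes, 24 of 26 were above sham at day 12 (median 0.37, or 0.23 with the marker score of other cells as a covariate), and 14 passed when adjusted over the list alone, including Sdf2l1, Hsp90b1 (0.68), Pdia4 (0.81 ± 0.24) and Hyou1 (0.72); 0 passed over all genes (camera adjusted p = 5.68e-13; adjusted p = 0.475 with an estimated correlation). Camera called 12 other lists higher: complement and antigen presentation (0.65, with C1s1 1.04 ± 0.67, Cd74 0.97 ± 0.46), interferon-stimulated genes (0.35, with Oasl2 0.96 ± 0.56, Gbp3 0.77 ± 0.42), NF-kB cytokines (0.29, with Ccl7 0.95 ± 0.45), immediate early genes (0.25, with Nr4a2 0.62 ± 0.29), extracellular matrix (0.34, with Fmod 1.01 ± 0.46) and TGF-beta signalling (0.24, with Thbs1 0.89 ± 0.67). The rest were mesothelial (0.85, with Aldh1a2 1.14 ± 0.74), fibroblast (0.44, with Pdgfra 0.79 ± 0.39), macrophage (0.44, with Ctss 0.86 ± 0.45), endothelial (0.38, with Vwf 0.88 ± 0.41), lymphocyte (0.32, with Jchain 2.24 ± 0.75) and adipocyte (0.25, with Scd1 1.32 ± 0.75) markers. All 12 calls were lost (lowest adjusted p = 0.475 with an estimated correlation). The 8 lists called lower were complex I (-0.11), complexes II to V (-0.09), the citric acid cycle (-0.09, with Suclg1 -0.28 ± 0.07), sarcomere proteins (-0.08, with Myot -0.29 ± 0.13, Pdlim5 -0.23 ± 0.06), glycolysis (-0.12, with Pfkp -0.40 ± 0.12), fatty acid oxidation (-0.07, with Acot1 -0.53 ± 0.34), heat shock proteins (-0.07, with Hspb3 -0.84 ± 0.22) and oxidative stress defence (-0.07, with Glrx -0.85 ± 0.16). These calls were lost too (lowest adjusted p = 0.475 with an estimated correlation). Without proton day 12 replicate 2, the medians of the immediate early, interferon, TGF-beta, extracellular matrix, complex I, fibroblast and macrophage lists changed sign, and that of the unfolded protein response was 0.20. Camera then did not call complement (0.03), NF-kB (0.04), endothelial (0.05), lymphocyte (0.14), adipocyte (0.01) or mesothelial (0.10) lists either.

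At day 26, genes of protein quality control in the endoplasmic reticulum rose and a carbonic anhydrase fell. Sdf2l1, on chromosome 16 from 17130138 to 17132383, was at 7.70 ± 0.14 (SD, n = 2) against 6.42 ± 0.17 in sham (SD, n = 3), 2.42-fold higher (log2 1.28 ± 0.16 SE; limma adjusted p = 0.0274). Syvn1, the ubiquitin ligase that marks misfolded proteins of that compartment for degradation, was 1.63-fold higher (log2 0.71 ± 0.11; adjusted p = 0.0499; chromosome 19, 6046576 to 6053718, overlapping Mrpl49). Pde7a was 1.65-fold higher (0.72 ± 0.09; adjusted p = 0.0274). Car14 fell by 0.56 ± 0.08 on the log2 scale (adjusted p = 0.0274; chromosome 3, 95897768 to 95905117, overlapping Aph1a), and the zinc finger gene Zfp991 fell by 0.98 ± 0.14 (adjusted p = 0.0304; chromosome 4, 147132093 to 147180579, overlapping Zfp978). In all 5 genes both day 26 samples lay on the same side of all 3 sham samples. Limma counted 1727 genes at an unadjusted p under 0.05, where 605 would be expected by chance, and the test without shared spread passed 0. The count of 5 became 0 without either proton day 1 replicate, proton day 5 replicate 3, proton day 26 replicate 1 or sham day 1 replicate 1, and 1 or 2 without proton day 3 replicate 1, proton day 26 replicate 2, sham day 1 replicate 2 or sham day 3 replicate 1. It was 29 without either proton day 12 replicate, 41 without proton day 3 replicate 3, and 0 with equal array medians or with all probe sets tested.

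The unfolded protein response list stood out at day 26. All 26 measured genes were above sham, with a median log2 difference of 0.57; 21 passed when adjusted over the list alone, and Sdf2l1 and Syvn1 passed over all genes. Other members were Pdia4 (1.15 ± 0.23), Edem1 (1.07 ± 0.32), Hyou1 (0.93 ± 0.18), Creld2 (0.84 ± 0.20), Manf (0.81 ± 0.13) and Hspa5 (0.59 ± 0.09), which encode chaperones, folding enzymes and degradation factors; these 6 were singled out after their values were seen. Camera called the list higher (adjusted p = 8.14e-17), the call was lost (adjusted p = 0.384 with an estimated correlation), and fry, which tests whether the genes move on balance in 1 direction, also called it (adjusted p = 0.0152). Cytosolic heat shock proteins had a median of 0.22, with Dnajb1 at 1.17 ± 0.58 and Hspa1a at 1.13 ± 0.55 (camera adjusted p = 0.00154; adjusted p = 0.611 with an estimated correlation). In that list 7 genes passed when adjusted over the list alone and 0 over all genes.

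Lymphocyte markers were higher at day 26 in all 11 measured genes, out of 26 in the list. Cd8b1 was 3.10 ± 0.55 above sham and Cd8a 1.67 ± 0.29, each just short of the threshold (limma adjusted p = 0.0528), and the list median was 0.80. In sham these 2 genes were at 4.31 and 4.62, below the signal filter of 5.00. The filter uses the mean over all arrays, so higher values in proton samples brought them past it. The same held for other genes named here or above, among them Hp (4.24 in sham), Jchain (4.11) and Cidec (4.3). A gene this low in sham was measured only if it was higher in proton samples. Medians and counts of higher genes in such lists thus depend in part on the filter. Camera called the list (adjusted p = 2.83e-05; adjusted p = 0.243 with an estimated correlation), as did fry (adjusted p = 0.0142); 6 genes passed when adjusted over the list alone and 0 over all genes. Complement and antigen presentation genes had a median of 0.65, with the class II genes Cd74 at 1.37 ± 0.46 and H2-Eb1 at 1.30 ± 0.37; 4 passed when adjusted over the list alone and 0 over all genes. Adipocyte markers had a median of 0.51 (Scd1 2.36 ± 0.75, Cidec 1.75 ± 0.59). Fibroblast markers had 0.58 (Thy1 1.40 ± 0.33, Pdgfra 1.22 ± 0.39), macrophage markers 0.53 (Laptm5 0.75 ± 0.48, Fcgr3 0.73 ± 0.43), endothelial markers 0.46 (Aqp1 1.05 ± 0.43) and smooth muscle markers 0.41 (Tagln 0.99 ± 0.31, Vtn 0.75 ± 0.31). Camera called these 6 lists higher and lost each (lowest adjusted p = 0.611 with an estimated correlation). Without proton day 26 replicate 1, fibroblast (0.34), endothelial (0.26), smooth muscle (0.155), adipocyte (0.225) and macrophage (0.45) markers were not called. Without replicate 2 the lymphocyte median was 0.51. Erythroid and platelet markers went the other way, with a median of -1.14 (Alas2 -1.87 ± 0.87, Slc4a1 -1.79 ± 0.73; camera adjusted p = 0.023; adjusted p = 0.611 with an estimated correlation).

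Other lists that camera called higher at day 26 were extracellular matrix (0.35, with Fmod 0.95 ± 0.46), TGF-beta signalling (0.30, with Thbs1 1.22 ± 0.67, Ccn2 0.91 ± 0.22), NF-kB cytokines (0.35, with Vcam1 1.08 ± 0.55, Icam1 1.06 ± 0.48), interferon-stimulated genes (0.29, with Tap1 0.85 ± 0.31) and immediate early genes (0.32, with Ccn1 0.82 ± 0.31). They moved with the fibroblast and macrophage markers above, and the calls were lost (lowest adjusted p = 0.611 with an estimated correlation). Lists called lower were complex I (-0.06, with Ndufb3 -0.48 ± 0.10), complexes II to V (-0.07, with Atp5pb -0.25 ± 0.08), the citric acid cycle (-0.06, with Pdhx -0.29 ± 0.10, Dlat -0.28 ± 0.08), sarcomere proteins (-0.06, with Xirp2 -0.31 ± 0.14), ion channels (-0.07), ribosomal proteins (-0.04, with Rpl24 -0.48 ± 0.15) and oxidative stress defence (-0.07). These 7 calls were lost (lowest adjusted p = 0.611 with an estimated correlation). Kcnh2, a potassium channel of repolarisation, was at -0.55 ± 0.10 (limma adjusted p = 0.0653), and Glrx, a thiol-repair enzyme, at -0.77 ± 0.16 (adjusted p = 0.0867). Without proton day 26 replicate 1, extracellular matrix (0.14), TGF-beta signalling (0.16), NF-kB cytokines (0.16), interferon-stimulated genes (0.22) and immediate early genes (-0.04) were not called, and the ribosomal median was 0.002 without sham day 1 replicate 1.

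**Figure D2:**
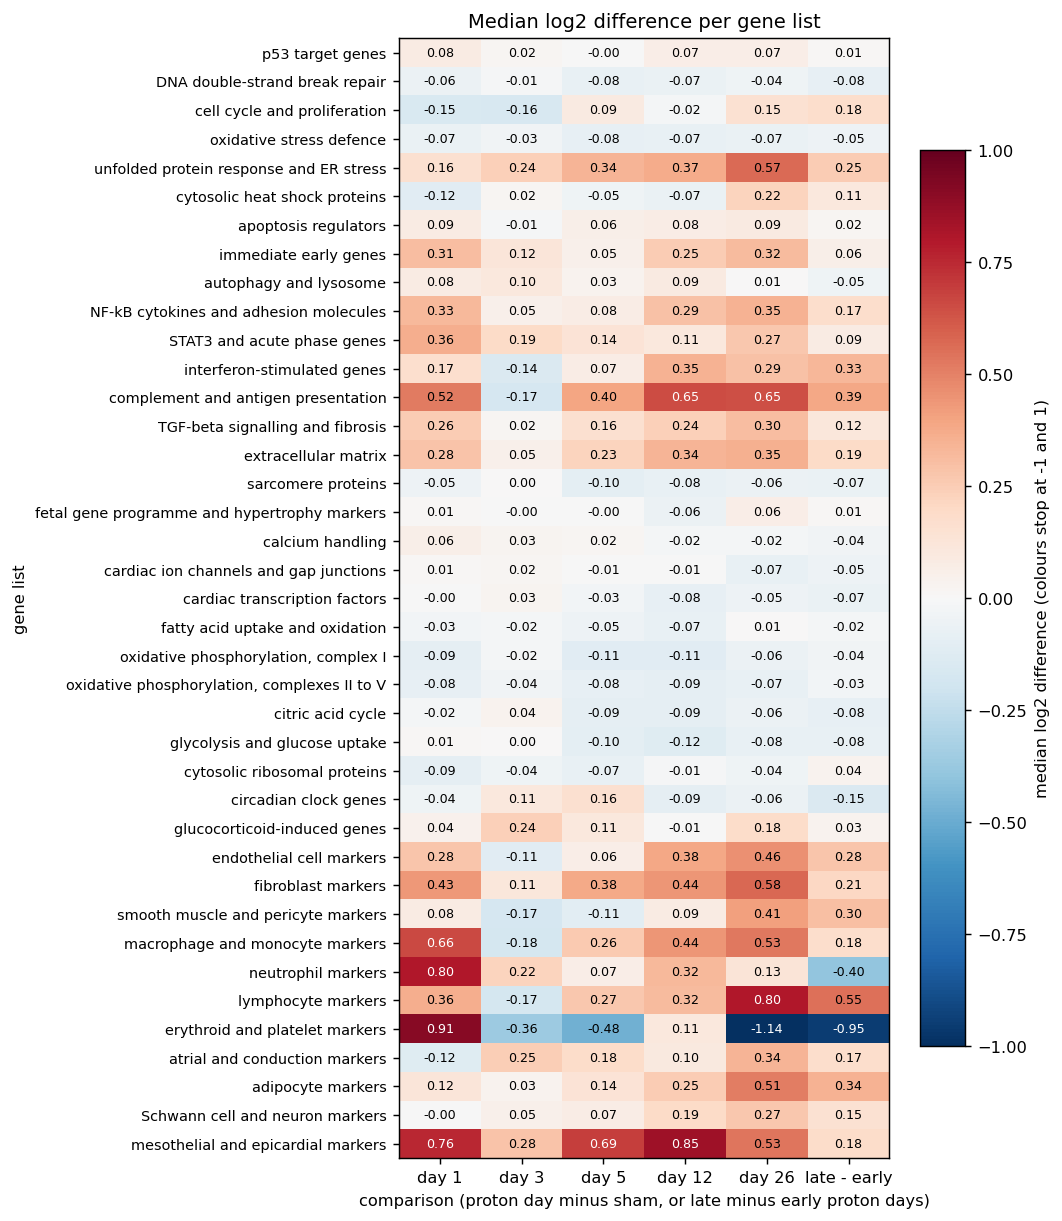
Median log2 difference of each of the 39 gene lists (y axis) in the 5 comparisons with sham and in late minus early proton days (x axis), as printed numbers and colours. The unfolded protein response list ran from 0.16 at day 1 to 0.57 at day 26, and erythroid and platelet markers from 0.91 to -1.14.

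The title of the series speaks of a delayed response, and the comparison of late days (12 and 26) with early days (1 and 3) addresses this without setting either against sham, although the sham samples enter the pooled spread of the test. Lcn2, an iron-scavenging protein of the acute phase, fell by 1.66 ± 0.19 on the log2 scale (SE; limma adjusted p = 0.0185). It was at 7.59 ± 0.41 (SD, n = 4) in late samples and 9.19 ± 0.38 (SD, n = 5) in early ones, with every late sample below every early sample; it lies on chromosome 2 from 32384637 to 32387739. The next 4 genes did not pass: Sdf2l1 at 0.89 ± 0.12 (adjusted p = 0.0562), and Ctnnal1 at -0.73 ± 0.11, Fxyd2 at 0.62 ± 0.09 and Phka1, a muscle subunit of phosphorylase kinase, at -0.78 ± 0.12 (each adjusted p = 0.0612). Limma counted 1602 genes at an unadjusted p under 0.05, and the test without shared spread passed 0. The count of 1 became 0 without either proton day 1 replicate, proton day 3 replicate 2, proton day 5 replicate 3 or proton day 26 replicate 1, or when only early and late samples entered the fit. It was 2 without proton day 3 replicate 1 or proton day 26 replicate 2, 3 without proton day 3 replicate 3 or proton day 12 replicate 2, 4 without proton day 12 replicate 1 and 6 without sham day 3 replicate 1. With the marker score of other cells as a covariate it was 389, and with all 15 arrays as separate samples 11.

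Among the lists, the unfolded protein response was higher late than early in 23 of 26 genes (median 0.25, with Pdia4 0.71 ± 0.17), and 12 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.26e-07; adjusted p = 0.398 with an estimated correlation). Lymphocyte markers (0.55, with Cd8b1 1.74 ± 0.41, Cd8a 0.95 ± 0.22), complement and antigen presentation (0.39, with Cd74 1.14 ± 0.34, H2-Ab1 1.12 ± 0.28), adipocyte markers (0.34, with Scd1 1.88 ± 0.55), interferon-stimulated genes (0.33, with Irf7 0.57 ± 0.17), smooth muscle markers (0.30, with Vtn 0.67 ± 0.23) and endothelial markers (0.28, with Aqp1 0.72 ± 0.32) were called higher by camera. So were fibroblast markers (0.21, with Pdgfra 0.79 ± 0.29), extracellular matrix (0.19, with Col8a1 0.53 ± 0.24), cell cycle genes (0.18, with Rrm2 0.51 ± 0.18) and heat shock proteins (0.11, with Dnaja1 0.53 ± 0.21). All 10 calls were lost (lowest adjusted p = 0.216 with an estimated correlation). Erythroid and platelet markers were called lower (-0.95, with Slc4a1 -1.53 ± 0.55), as were clock genes (-0.15) and, with small medians, the citric acid cycle (-0.08), glycolysis (-0.08, with Bnip3 -0.34 ± 0.14), sarcomere proteins (-0.07, with Nebl -0.29 ± 0.08), cardiac transcription factors (-0.07, with Hand2 -0.39 ± 0.12), ion channels (-0.05, with Kcnh2 -0.44 ± 0.08), oxidative stress defence (-0.05, with Gclm -0.53 ± 0.10), calcium handling (-0.04, with Slc8a1 -0.33 ± 0.10), complex I (-0.04) and complexes II to V (-0.03). These 11 calls were lost too (lowest adjusted p = 0.216 with an estimated correlation). Fry called lymphocyte markers and glycolysis (each adjusted p = 0.0375). Without proton day 12 replicate 2, the medians of the extracellular matrix, complex I and fibroblast lists changed sign, and that of the unfolded protein response was 0.16.

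The genes of the unfolded protein response were also averaged per sample, as deviations from each gene's mean. The mean was -0.26 ± 0.04 in sham (SD, n = 3), -0.09 ± 0.04 at day 1 (SD, n = 2), -0.01 ± 0.16 at day 3 (SD, n = 3), 0.07 ± 0.01 at day 5, 0.11 ± 0.24 at day 12 and 0.32 ± 0.15 at day 26 (SD, n = 2 each). All 11 proton samples lay above all 3 sham samples, with a mean difference of 0.33; 4 of the 364 splits of the 14 samples gave a difference as large (2-sided exact permutation p = 0.011; adjusted over 39 lists, p = 0.429). Over the 11 proton samples the mean went up with the day (Pearson r = 0.76, permutation p = 0.00688, adjusted 0.0138; Spearman rho = 0.75, permutation p = 0.00997, adjusted 0.0199). Without the day 26 samples r was 0.49 (exact p = 0.173, n = 9). Passing the threshold thus depended on those samples, and the lower r came with fewer samples and a shorter span of days. The permutations treated the 11 proton samples as independent. Samples of the same day may share mice or handling, which these p-values do not measure. The same mean also went up with the score of endothelial, fibroblast and macrophage markers (r = 0.653, permutation p = 0.0308; rho = 0.664, permutation p = 0.031; both unchanged by adjustment over these 2 relations). Without proton day 3 replicates 1 and 2 that r was 0.544 (exact p = 0.13, n = 9), of similar size but no longer past the threshold with fewer samples. The labels name no batch or processing date, so no within-batch value could be given.

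**Figure D3:**
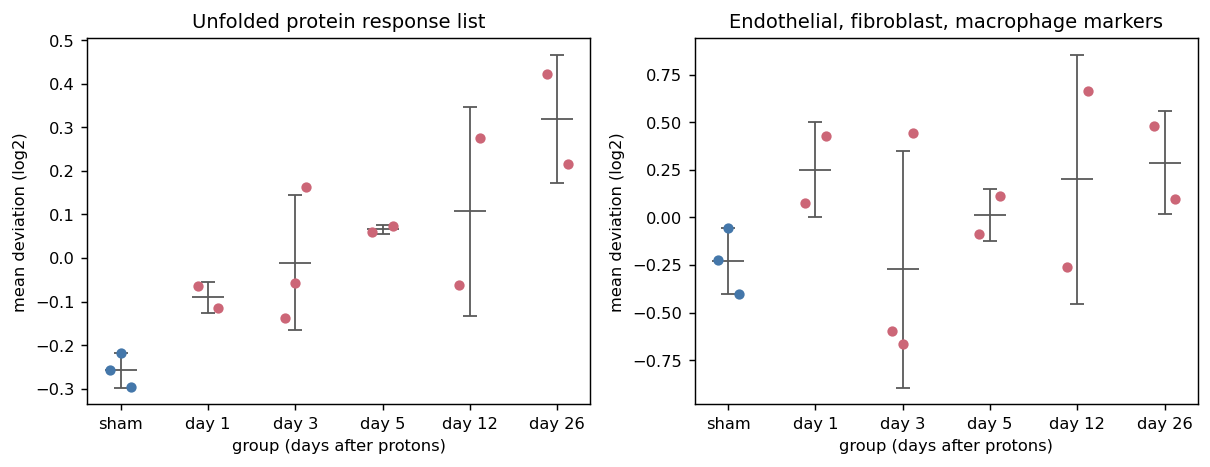
Mean deviation (log2) of the unfolded protein response list (left) and of the endothelial, fibroblast and macrophage marker lists (right) in sham samples and at each day after protons. Points are samples, long bars group means and short bars 1 SD; on the left every proton sample lies above the sham samples, which run from -0.30 to -0.22.

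The difference among the 5 proton days was tested as well. Limma passed 0 genes, with 1020 at an unadjusted p under 0.05, and the test without shared spread passed 0. The smallest p-values belonged to Pde7a and Rnu12 (adjusted p = 0.0868), Lcn2 and Ctnnal1 (0.109), Rnf144b (0.129), the clock gene Arntl (0.19), Sdf2l1 and Dbp (0.203), and Dhrs7c and Phka1 (0.204). The count was 2 without proton day 3 replicate 3 or sham day 1 replicate 2, 4 without proton day 12 replicate 2 and 5 without sham day 3 replicate 1.

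Clock genes went in opposite directions within their list. Late against early, the activator Arntl was at 0.34, while its targets Dbp (-0.50 ± 0.09), Ciart (-0.94 ± 0.21) and Per3 (-0.36) were below 0. These 4 passed when adjusted over the list alone, and 0 of the 21 measured genes passed over all genes. Camera called the list lower (adjusted p = 0.0062; adjusted p = 0.398 with an estimated correlation), and fry's test for change in either direction called it (adjusted p = 0.000456). That test also called it at day 12 (adjusted p = 0.000127) and day 26 (adjusted p = 0.000738), where Nfil3, a repressor of clock output, was at 0.75 ± 0.14 and Ciart at -1.13 ± 0.28. It was not confined to clock genes, since the same test called 14 of the 39 lists late against early and 9 at day 26, against 1 at day 12. At day 5, Arntl was at -0.50 ± 0.13 and Per2 at 0.49 ± 0.23.

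**Figure D4:**
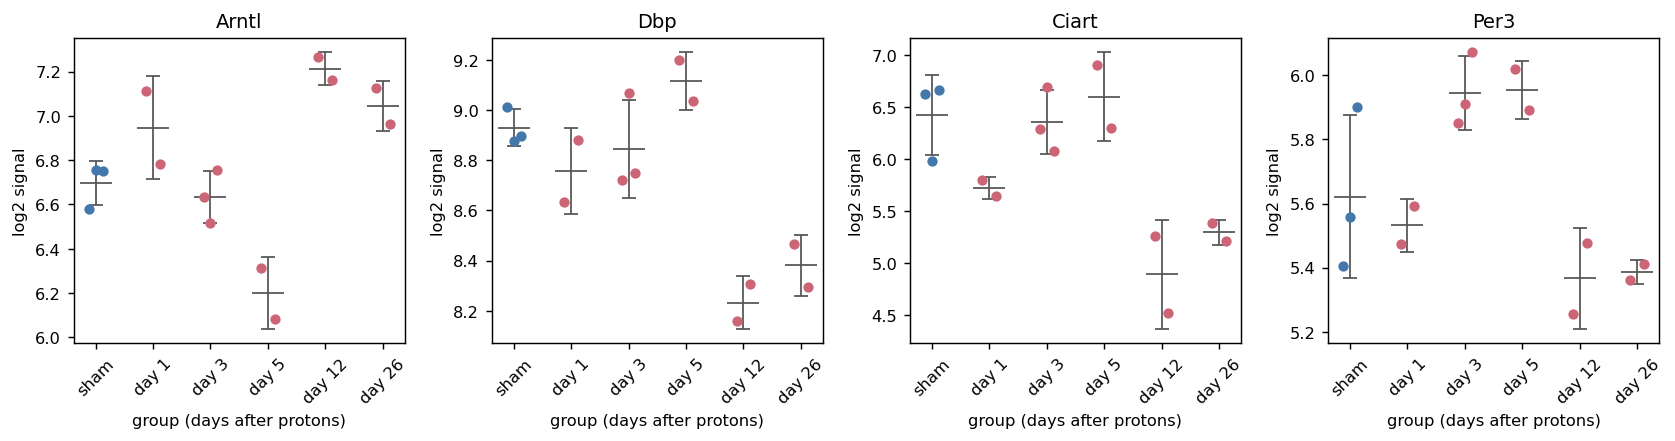
Log2 signal of the clock genes Arntl, Dbp, Ciart and Per3 (y axes) in sham samples and at each day after protons (x axes). Points are samples, long bars group means and short bars 1 SD; Dbp had a mean of 8.23 at day 12 and 8.93 in sham.

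Genes fixed for every comparison gave few differences. Of the p53 targets, which answer DNA damage, Phlda3 was above sham at each day (0.51 ± 0.12, 0.23 ± 0.10, 0.35 ± 0.12, 0.24 ± 0.12 and 0.57 ± 0.12 at days 1, 3, 5, 12 and 26) with a lowest adjusted p of 0.0867, at day 26. Mdm2 lay between -0.05 and 0.04 and Ccng1 between -0.15 and -0.03. Trp53inp1 lay between 0.60 and 0.86 above sham at the 5 days with no adjusted p under 0.269. The load marker Nppa was at -0.27 ± 0.40, 0.50 ± 0.36, 0.17 ± 0.40, -0.40 ± 0.40 and 0.37 ± 0.40, and Nppb between -0.11 and 0.24. Of contractile genes, Myh6 lay between -0.05 and 0.05, Atp2a2 between 0.01 and 0.03, Myh7 between -0.26 and 0.41 and Acta1 between -0.58 and -0.30. Gata4 lay between -0.32 and -0.05, Stat3 between -0.09 and 0.34, Hmox1 between -0.09 and 0.21, and Tgfb1 between -0.24 and 0.28. None of these passed in any comparison with sham. Cdkn1a, Bax and Nfkb1 had no probe set of their own in the annotation, and Il6 was below the signal filter (mean 3.08), so these 4 were not tested. The lists of DNA double-strand break repair (medians -0.08 to -0.01), apoptosis regulators (-0.015 to 0.093), fetal and hypertrophy genes (-0.06 to 0.06) and Schwann cell and neuron markers (-0.002 to 0.270) were called by camera in no comparison. Single fetal genes differed more at day 26: Myl7 was 4.9-fold (limma adjusted p = 0.17) and Myl4 3.99-fold higher (adjusted p = 0.286). For each, both day 26 samples lay above all sham samples. Fry's test for change in either direction called the fetal list there (adjusted p = 0.0136). Both genes also stand in the atrial list (day 26 median 0.34, not called by camera). Its sample means were 0.771 and 0.026 in day 26 replicates 1 and 2. For every list that camera called, the median, the mean and the direction of the test had the same sign.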

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

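Of the tests in this part, the splits for late against early days and the correction of the unfolded protein response for other cells at day 26 were planned before their results were seen, and the same correction at day 1, the other splits, the score within the day assignments, the marker tests and the clock tests were chosen afterwards.

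Late and early days after protons differed in 1 gene (389 with the non-cardiomyocyte score as a covariate, 11 with all 15 arrays as separate samples). Camera called 22 of 39 lists at its preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.216). Lcn2 had a late minus early log2 difference of -1.66. The real assignment of the 9 samples to these 4 days and 99 random ones were compared: 16 of the 100 passed at least 1 gene, against 1 in the real one and up to 1672 in another. Chance cannot be excluded for this count. Of the 100, the assignment with 1672 genes had the largest late minus early difference of the non-cardiomyocyte score (0.834) and the smallest SD of the score within days (0.147), against 0.255 and 0.517 in the real one. It was picked for its count, and the score comes from the same expression values, so this does not test a cause. Over the 100 assignments, the count of genes and the size of the score difference had a Spearman correlation of 0.42. At day 3 against sham, 2 of the 10 possible splits passed as many genes as the real one, which passed 1, and the highest other count was 1; 10 splits are too few for a share under 0.05.

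The lists that camera called between late and early days at its preset correlation had these median log2 differences. Above 0 were lymphocyte markers 0.547, complement and antigen presentation 0.389, adipocyte markers 0.344, interferon-stimulated genes 0.333, smooth muscle and pericyte markers 0.3, endothelial markers 0.281, the unfolded protein response 0.254, fibroblast markers 0.209, extracellular matrix 0.192, cell cycle genes 0.176 and cytosolic heat shock proteins 0.107. Below 0 were erythroid and platelet markers -0.947, clock genes -0.147, the citric acid cycle -0.081, glycolysis -0.076, cardiac transcription factors -0.068, sarcomere proteins -0.066, ion channels -0.05, oxidative stress defence -0.048, calcium handling -0.038, oxidative phosphorylation complex I -0.037 and complexes II to V -0.031. All 22 calls were lost (lowest adjusted p = 0.216 with an estimated correlation). In 2 of the 100 simulated data sets without a group difference, camera called as many lists, with a median of 13.5 and a highest count of 22. For the comparisons with sham, at least as many lists as in the real data were called in 21, 98, 62, 5 and 1 of 100 at days 1, 3, 5, 12 and 26.

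The unfolded protein response list was higher in all 11 proton samples than in all 3 sham samples. More endothelial, fibroblast and macrophage cells, as far as their marker score measures them, are argued against as the whole cause at day 26. With the score as a covariate, 72.6% of the day 26 median was kept (0.566 without and 0.411 with it). The corrected list mean still differed by 0.249 (5 of 364 splits as large, exact permutation p = 0.0137), with 10 of 11 proton samples above all sham. Lymphocyte, adipocyte and smooth muscle markers, also higher at day 26, are not part of the score, so a larger share of other cells stays open. At day 1 more cells of the scored types may be the cause, since 17.1% of the median was kept (0.164, quartiles 0.083 and 0.263, without the covariate and 0.028, quartiles -0.056 and 0.121, with it) and the camera call ended (adjusted p = 0.078) because the difference itself shrank. Chance is argued against for this list taken alone, where 4 of 364 splits gave a difference as large as the real 0.328 (highest other 0.388). None of 100 simulated data sets without a group difference reached its medians at day 12 (0.371, highest 0.355) or day 26 (0.566, highest 0.307), against 21, 5 and 3 at days 1, 3 and 5. The splits and both medians share the same 3 sham samples, so they do not count as separate evidence. Without proton day 12 replicate 2 the day 12 median was 0.20. Chance stays open over the 39 lists from which this one was picked (exact permutation p adjusted over them 0.429). A difference that lies in the sham samples alone, such as their day or handling, cannot be told apart from an effect of protons, and both stay open: the list mean was 0.256 higher late than early, which does not use sham, but 8 of 126 splits were as large (exact permutation p = 0.0635).

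Endothelial, fibroblast and macrophage markers varied together between samples of the same group. Deviations from the group means correlated between these lists with r of 0.838, 0.926 and 0.953, which is what a varying share of such cells in the suspension may give; 10 of the 19 measured fibroblast genes, 4 of 23 macrophage genes and 1 of 24 endothelial genes also stand in another list. Abundant members were at high signals, with Dcn at 10.57 in sham and 11.17 at day 26, Lyz2 at 9.53 and 10.01, and the endothelial Fabp4 at 9.31 and 9.4 and Eng at 8.48 and 9.17, although the protocol selected calcium-tolerant cardiomyocytes. A lower share of cardiomyocytes that raises all other cells alike at day 26 is argued against by erythroid and platelet markers, which differed from the score of the other 3 lists by -1.404 ± 0.292 (SE), at -0.889 ± 0.542 against 0.515 ± 0.384. A change in which cells came along, or in the blood left in the heart, stays open, and no biological explanation was tested.

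Clock genes differed between proton days in opposite directions. The mean of 11 genes grouped with Dbp was subtracted from the mean of 4 genes grouped with Arntl. Averaged by day, this difference was 0.438 ± 0.094 (SE) higher late than early, as a shared shift of clock phase may give. Not every gene followed its arm. Hlf and Nr1d2, grouped with Dbp, were on average not lower late than early, and Clock, grouped with Arntl, was not higher. For the arm difference, the exact permutation test compared the means of all late and all early samples instead (p = 0.0238 over 126 splits). The arm difference was -0.09 ± 0.08 in sham (SD, n = 3), 0.18 ± 0.20 at day 1 (SD, n = 2), -0.21 ± 0.10 at day 3 (SD, n = 3), -0.57 ± 0.17 at day 5, 0.46 ± 0.22 at day 12 and 0.39 ± 0.10 at day 26 (SD, n = 2 each). Early and late samples overlapped, since the higher day 1 sample (0.316) equalled the lower day 26 sample and day 1 lay on the late side of sham. The labels give a time of day for 0 samples, so the hour of cell isolation cannot be told apart from an effect of protons on the clock, and both stay open.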

How the results depend on the processing

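Of the settings in this part, all 15 arrays as separate samples and the non-cardiomyocyte score as a covariate were chosen after the data had been seen. Comparisons with sham are named by their day, late stands for late against early days, any for any proton day against sham and among for the test among proton days. The counts to compare with are 0 at day 1, 1 at day 3, 6 at day 5, 0 at day 12, 5 at day 26, 1 late, 3 any and 0 among. The cause of a changed count was not tested, except that settings with other genes tested or fewer samples differ by construction. The pooled sham, the few arrays and the unknown background level of the arrays limit all of these values.

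Quantile normalization gave 3 genes at day 3, 26 at day 26 and 3 late. Equal array medians gave 2 at day 3, 0 at day 26 and 0 any. Without a filter 12 genes passed at day 26, and with the stricter filter 23 at day 26 and 7 late. All probe sets gave 31 at day 3, 10 at day 5, 0 at day 26 and 1 any, and the mean of a gene's probe sets gave 3 at day 3. Without a variance trend the counts were 3 at day 3, 1 at day 5, 3 at day 26, 2 late and 1 any, and with a robust variance 5 at day 3, 25 at day 26 and 4 late. Array weights gave 1 at day 1, 4 at day 3, 47 at day 5, 309 at day 26, 2 late, 55 any and 20 among. The test without shared spread gave 0 at days 3, 5 and 26, 0 late and 1 any. A fit of only the groups compared gave 0 at day 3, 11 at day 5, 46 at day 26 and 0 late. With sham of day 1 only, 2 genes passed at day 3, 2 at day 26 and 8 any, and the time-matched sham gave 4 at day 3; days 5, 12 and 26 have no such sham. The 2 pseudocounts were not run, as the values were already logarithms. All 15 arrays as separate samples gave 5 at day 3, 32 at day 5, 2 at day 12, 54 at day 26, 11 late, 28 any and 11 among. The covariate gave 3 at day 1, 107 at day 3, 17 at day 5, 1 at day 12, 126 at day 26, 389 late, 129 any and 57 among.

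With a replicate block the counts were 0 at day 5, 0 at day 26, 3 late, 0 any and 1 among, and 3 list medians changed sign: glucocorticoid genes at day 3 to -0.00873, and at day 5 extracellular matrix to -0.0282 and fibroblast markers to -0.0105. This setting was run without the sham day 3 sample, so the block and the smaller control cannot be told apart.

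Leaving out 1 array at a time gave counts of 0 to 1 at day 1, 1 to 5 at day 3, 0 to 7 at day 5, 0 to 1 at day 12, 0 to 41 at day 26, 0 to 6 late, 0 to 8 any and 0 to 5 among. Where this left a group with 1 sample, that sample was assumed to vary like the other groups.

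With the covariate, list medians changed sign for complement and antigen presentation (-0.108), extracellular matrix (-0.13), endothelial (-0.0874), fibroblast (-0.0511) and mesothelial markers (-0.0671) at day 1. They did so for extracellular matrix (-0.0198), fibroblast (-0.011) and macrophage markers (-0.0575) at day 12. At day 26 they did so for interferon-stimulated genes (-0.00745), extracellular matrix (-0.0182), complex I (0.00948), ribosomal proteins (0.00594), fibroblast (-0.0241) and macrophage markers (-0.112), and late for extracellular matrix (-0.00243), complex I (0.00471) and fibroblast markers (-0.054). The score is built from 3 of these lists, so a sign near 0 is fixed in part by its construction. With these medians below 0, camera at its preset correlation still called macrophage markers at day 26 (adjusted p = 0.0309). It also called extracellular matrix, which is not in the score, at day 1 (adjusted p = 0.00121). Leaving out 1 array at a time also changed signs. At day 12 the medians ran from -0.0692 to 0.595 for immediate early and -0.0106 to 0.663 for interferon-stimulated genes, -0.0342 to 0.502 for TGF-beta signalling, -0.0738 to 0.712 for extracellular matrix, -0.228 to 0.00796 for complex I, -0.0725 to 0.985 for fibroblast and -0.118 to 1.04 for macrophage markers. Late medians ran from -0.0116 to 0.399 for extracellular matrix, -0.102 to 0.0199 for complex I and -0.0164 to 0.466 for fibroblast markers. In all of these, 1 end came without proton day 12 replicate 2 and the other without replicate 1 of that day. At day 26 immediate early genes ran from -0.0419 without proton day 26 replicate 1 to 0.543 without replicate 2, and ribosomal proteins from -0.0664 to 0.00202, the latter without sham day 1 replicate 1.

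No called gene changed sign in any setting run. This was largely fixed in advance, since the samples of these genes did not overlap those they were compared with. Several settings also leave the log2 difference unchanged. Pde7a at day 3 passed in 28 of 31 settings and Scarna13 at day 5 in 27 of 30. Sdf2l1 at day 26 passed in 17 of 30, Syvn1 in 12 of 30, and Lcn2 late in 22 of 29. Over the named genes, 2985 values stayed on their side of the threshold, 130 fell short of it, 62 newly passed and 99 that passed in neither setting changed sign. Over the lists called by camera, 2481 values kept the call and 395 lost it. The unfolded protein response list was called in 27 of 28 settings at day 1 and in all 28 settings at days 3, 5, 12 and 26. Of those 28, 1 was missing at day 1, with the covariate (camera adjusted p = 0.078, median 0.03). All these settings used the preset correlation, at which camera also called this list in many simulated data sets without a group difference. It did so in 50, 59, 51, 51 and 51 of 100 at days 1, 3, 5, 12 and 26, and in 44 late. A call in every setting thus says little by itself, and with an estimated correlation the list was called at no day. Its median ran from 0.03 to 0.22 at day 1, 0.14 to 0.30 at day 3, 0.25 to 0.39 at day 5, 0.20 to 0.52 at day 12, 0.41 to 0.65 at day 26 and 0.16 to 0.34 late. Of the 98 lists called by camera, 78 had a median that leaving out 1 array moved by over 1.5 times or past 0. Equal array medians moved the median of all genes at day 26 by -0.105 (0.052 before and -0.053 after) and late by -0.092; relative to the median of all genes, the list medians at day 26 are thus lower by 0.05 as reported and higher by 0.05 under this setting. Every other such move was at most 0.059 in size.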

Other observations

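The grouping of small RNA genes and every test on it were chosen after the values had been seen, while the gene lists of the last paragraph were not.

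Small RNAs of the nucleus moved together at day 5. Of 43 measured genes for snoRNAs, scaRNAs and snRNAs, which guide modification of ribosomal and spliceosomal RNA or take part in splicing, all 43 were above sham, with a median log2 difference of 0.61, and 5 passed over all genes. The medians were 0.18 at day 1, 0.01 at day 3, 0.39 at day 12 and 0.50 at day 26. Camera with an estimated correlation gave p = 0.158, 0.657, 0.00915, 0.0389 and 0.0673 at days 1, 3, 5, 12 and 26 and 0.107 late against early, unadjusted and on a group picked for its largest members. The group mean was 0.36 higher in proton than in sham samples (17 of 364 splits as large, exact permutation p = 0.0467; 9 of 11 proton samples above all sham) and 0.31 higher late than early (2 of 126 splits, exact permutation p = 0.0159). The sham day 3 sample lay at -0.504, against -0.169 and -0.174 for those of day 1, and without it the difference was 0.249 (16 of 78 splits as large, exact permutation p = 0.205). The 18 measured host genes had medians from -0.054 to 0.053 over the 5 days. The hosts of Scarna13, Snora16a and Snora73b (Snhg10, Snhg12 and Snhg3) were not among them, so their levels are not known. The 66 measured microRNA genes had medians of -0.076, 0.025, 0.095 and 0.057 at days 1, 3, 5 and 12 and of 0.271 at day 26, where 58 were above sham (unadjusted camera p = 0.301 with an estimated correlation). Late against early their median was 0.197, with 55 of 66 higher (p = 0.375 with an estimated correlation).

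The late decline of Lcn2 was seen in part of its list. In the STAT3 and acute phase list, Lcn2, Serpina3n (-0.89) and Stat3 (-0.32) were below their early levels and passed when adjusted over the list alone, and 11 of the 18 measured genes were higher late than early. The list had a late minus early median of 0.085 and a mean of -0.127, so the median and the mean differed in sign. Cytosolic heat shock proteins varied among the sham samples themselves: their list mean ran from -0.26 to 0.19 in sham and was 0.30 and 0.32 in the day 26 samples. Dnajb1 ran from 7.05 to 9.58 in sham, and Hspb3, a small heat shock protein of muscle, was below sham at day 12 (-0.84 ± 0.22).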
